A study of Arabidopsis thaliana with 6 samples.

How the data were processed

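Total RNA from 12-day-old Arabidopsis thaliana seedlings was sequenced as single-end reads of 50 bases on an MGISEQ-2000 instrument. Per the labels, seedlings grew on MS medium under 16 h of light and 8 h of dark at 22 °C, and RNA was extracted with TRIzol. There were 6 libraries, 2 each from the wild-type accession Col-0, from hac1hac5 plants and from med8med25 plants, and each library was placed in its genotype by its own label. Nothing in the labels says that the 2 libraries of a genotype came from separately grown plants, so p-values measure only the spread between these samples, which may be technical.

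The authors deposited 1 table of gene values per library, in a normalized signal and not in raw reads. HISAT2, featureCounts and edgeR are named in the submitters' processing notes, with genome build TAIR10. Versions, the annotation, the strand setting and the rule for reads on several genes were not given in the sources used here. The values were not whole, and the deposited signal summed to between 30.3 and 35.5 M per library. All 195288 values were equal, within a relative difference of 1e-06, to those that a quantile adjustment to a common effective library of 32.6 M reads gives from whole read counts, with 7 fitted parameters including a common dispersion of 0.00697. The largest relative difference was 5.3e-09. The adjustment was tested on simulated data, where 100% of 195288 values were recovered. The deposited values are called normalized counts below, and the recovered whole reads were used for depth and for the alternatives named below.

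Recovered depth was 36.2 and 33.1 M reads for the Col-0 libraries, 33.9 and 36.8 M for hac1hac5, and 24.9 and 32.3 M for med8med25. The authors' normalization factors, as recovered, were 0.932 and 0.917, 1.065 and 1.03, and 0.991 and 1.075 in the same order. PCR reads without molecular identifiers are not independent molecules, so depth describes counting error only. The first med8med25 library was the shallowest, and values near 0 carry little information in every library. Of 32548 gene IDs, 6389 had no read in any library.

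The tests planned for raw counts were replaced by limma-trend because the values were a normalized signal, and were not run on the recovered reads. The test was run on log2(normalized count + 1), over 23898 genes with a value of at least 1 in at least 2 libraries, with genotype as the only term and all 6 libraries sharing an estimate of the spread (3 residual degrees of freedom, 5.3 prior degrees of freedom). Every log2 fold change is on this scale, which understates the change of weakly expressed genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. A value quoted as an adjusted p comes from limma unless a list is its subject. In a self-test on counts simulated for hac1hac5 against Col-0 over 23918 genes, changes of 1.25-fold, 1.5-fold and 2-fold were called in 7.6%, 43.3% and 71.2% of the changed genes. Of genes with a mean of at least 5 CPM, 12.5%, 69.0% and 100% were called. Unchanged genes made up 14.7% of those calls (14 genes), above the share of 0.05 that the threshold aims at. Another 6 genes were called in the simulated med8med25 comparison without any change. The self-test held 66, 67 and 66 changed genes for the 3 sizes of change. This is far fewer than were called in the data, so its shares may not carry over.

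Gene names came from the TAIR10.1 RefSeq gene table, which matched all 32548 IDs and gave 10804 of them a symbol. Its exons were used to find which genes overlap and which 50-base windows are unique. No position is given because the annotation used by the authors is not stated.

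The 24 gene lists hold 386 members. They cover the targeted genes, other histone acetyltransferases, other Mediator subunits, floral repressors, floral activators, the autonomous flowering pathway, jasmonate synthesis and MYC-branch response, jasmonate and ethylene ERF-branch defence, ethylene response, salicylate immunity, cold and dehydration response, touch and handling response, heat shock proteins, nuclear photosynthesis genes, flavonoid and anthocyanin synthesis, glucosinolate metabolism, iron deficiency response, auxin response, the circadian clock, senescence and sugar starvation, root hair markers, other root markers, seed storage and embryo markers, and floral organ identity markers. Members were matched by gene ID and symbol (353) or by gene ID where the reference table gives no name (26). Another 6 (MED2, MED5A, MED5B, MED13, MED15 and FIT) were dropped because ID and symbol did not match, and AOP2 had no value. Lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated for each list and limma fry, which asks whether the members of a list move one way on balance without comparing them with other genes, were alternatives.

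Groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names HAC1, HAC5, MED8, MED25, FLC and FT in any case. For each mutant against Col-0 it names the 10 higher and 10 lower genes with the largest absolute log2 fold change among called genes that had both mutant libraries on the same side of both Col-0 libraries and a mean of at least 5 CPM (163 normalized counts) in the higher genotype. It names up to 4 called members per list and mutant with the smallest adjusted p, or the 2 with the smallest adjusted p where none was called. It names the 5 genes per direction changed most in both mutants by the smaller of their 2 changes, and 5 per direction between the mutants.

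The alternatives fixed with them, carried over to limma, were median-of-ratios scaling, no filter on low values, a filter of 1 CPM in 2 libraries, fits with only the 2 genotypes compared, the replicate number as a block, a pseudocount of 0.1, a minimum absolute log2 fold change of 1, and leaving out each library in turn. After the data were seen, limma voom on the recovered whole reads and scaling to total recovered reads were added. Scaling to totals moved the median log2 fold change by 0.18 in hac1hac5 and 0.158 in med8med25, so changes are reported relative to the authors' scaling. No library was left out of the values below.

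Both mutants are compared with the same Col-0 libraries. Overlaps and correlations are therefore given beside 100 simulations of unchanged groups against those libraries and beside the overlap of independent lists. Fits and list tests used R 4.3.3 and limma 3.58.1, and other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.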

Results

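Transcript levels were measured by RNA-seq in 12-day-old Arabidopsis seedlings of 3 genotypes, with 2 libraries each. Col-0 is the wild type. The hac1hac5 plants carry mutations in HAC1 and HAC5, which encode histone acetyltransferases of the CBP/p300 family. The med8med25 plants carry mutations in MED8 and MED25, which encode subunits of Mediator, the complex that links transcription factors to RNA polymerase II. Depth ran from 24.9 to 36.8 M reads per library. Across 18807 expressed genes the 2 libraries of a genotype correlated at r = 0.9964 in Col-0, 0.9939 in hac1hac5 and 0.9894 in med8med25, and the SD of their log2 difference was 0.18, 0.227 and 0.308. Replicates differed by more than sampling noise in each genotype (chi-square per gene of 3.26, 11.08 and 22.02), which repeat preparations of 1 RNA could also do. The first principal component held 64.3% of the variance and set hac1hac5 apart from the other genotypes, and the second held 27.9% and separated med8med25 from Col-0.

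The targeted genes were examined first. MED8 (AT2G03070) was at 846.6 and 855.3 normalized counts in Col-0, 900.1 and 864.3 in hac1hac5, and 307.1 and 322.9 in med8med25. MED25 (AT1G25540) was at 1236 and 1227 in Col-0, 1001 and 1178 in hac1hac5, and 253.8 and 302.4 in med8med25. Both fell in med8med25, MED8 2.70-fold (log2 change -1.43, SE 0.08, adjusted p = 2.0e-05) and MED25 4.43-fold (log2 change -2.15, SE 0.11, adjusted p = 1.4e-05). HAC1 (AT1G79000) was at 3385 and 3529 in Col-0, 2342 and 2875 in hac1hac5, and 3484 and 3383 in med8med25. Its decrease in hac1hac5 was small (log2 change -0.41, SE 0.10, adjusted p = 0.011), and the call was lost without the first or second Col-0 library (-0.44 and -0.38), without the first hac1hac5 library (-0.27) and with total-count scaling (-0.23). HAC5 (AT3G12980) was at 1233 and 1190 in Col-0, 800.7 and 1087 in hac1hac5, and 1131 and 1195 in med8med25, and was not called in hac1hac5 (log2 change -0.38, SE 0.13, adjusted p = 0.05). It was called without the second hac1hac5 library (-0.60), and with the 1 CPM filter, limma voom or the replicate block (-0.38). Reads upstream or downstream of an insertion can remain in a mutant, so levels of HAC1 and HAC5 check the hac1hac5 label only in part. As a list, the targeted genes had 1 lower member of 4 in hac1hac5 (2 adjusted over the list alone; camera adjusted p = 0.36) and 2 lower in med8med25 (2 adjusted over the list alone; camera adjusted p = 0.054), where the list passed with no filter, limma voom or total-count scaling.

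**Figure D1:**
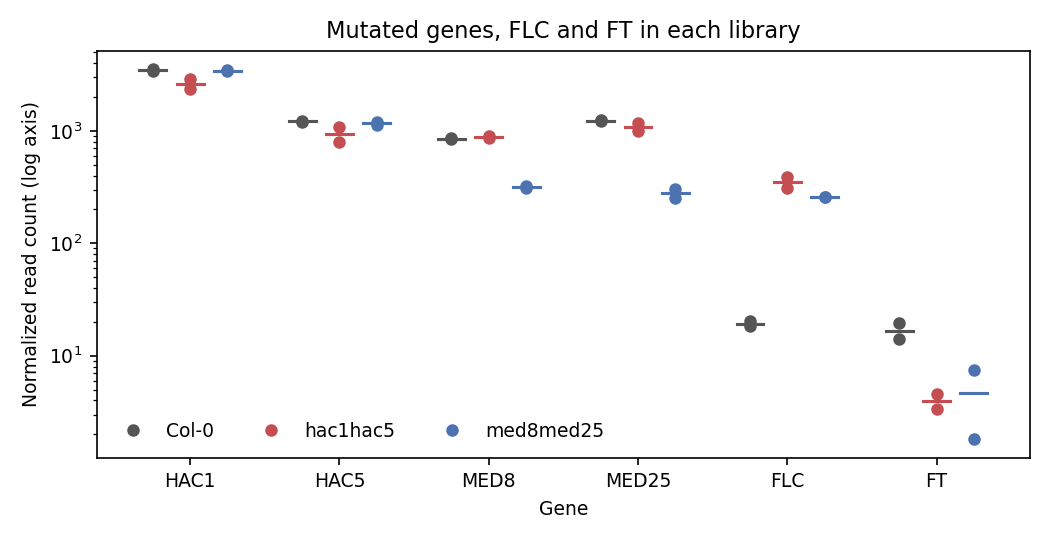
Normalized read counts of HAC1, HAC5, MED8, MED25, FLC and FT on a log axis, with a point per library, a bar at each genotype mean (n = 2) and colours for the 3 genotypes. MED8 and MED25 lay at 253.8 to 322.9 in med8med25, HAC1 and HAC5 lay lower in hac1hac5 by less than 1 on the log2 scale, and FLC was at 258.0 to 386.9 in the mutants against 18.28 and 20.31 in Col-0.

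The comparison of hac1hac5 with Col-0 asks which transcripts differ when HAC1 and HAC5 are mutated. The touch, jasmonate and cold lists had the largest median increases, and the auxin response and iron deficiency lists the largest median decreases. Growth or harvest conditions that differed between the genotypes could add to these and to all other differences between genotypes given below. Such conditions cannot be told apart from an effect of the mutations. ZAT10, a zinc-finger repressor induced by many stresses, rose from 79.5 ± 13.5 to 9124 ± 956 normalized counts (SD, n = 2, log2 change 6.83, SE 0.12, adjusted p = 4.7e-08). OPR3, an enzyme of jasmonate synthesis, rose 11.9-fold from 774.8 ± 22.8 to 9233 ± 379 (SD, n = 2, adjusted p = 1.5e-07). IAA29, an auxin-induced Aux/IAA repressor, fell 16.7-fold from 4906 ± 403 to 295.3 ± 61.1 (SD, n = 2, adjusted p = 9.4e-06). FLC, the MADS-box repressor of flowering, rose 17.2-fold from 19.3 ± 1.43 to 349.3 ± 53.1 (SD, n = 2, adjusted p = 1.4e-06), and 12.0% of its read-length windows are free of other annotated genes.

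All 15 tested touch and handling genes rose (15 adjusted over the list alone; camera adjusted p = 5.0e-13, adjusted p = 0.29 with an estimated correlation), among them the transcription factor WRKY40 (log2 change 5.60) and the zinc-finger genes SZF1 (4.36) and SZF2 (3.47). In the jasmonate synthesis and MYC-branch list, 19 of 23 members rose and 3 fell (19 and 4 adjusted over the list alone; camera adjusted p = 5.8e-08, adjusted p = 0.38 with an estimated correlation). The jasmonate repressor genes JAZ9 and JAZ2 changed by 3.02 and 2.51 on the log2 scale, and AOC3, a cyclase of jasmonate synthesis, by 3.68. The members that fell were LOX2 (-0.69), AOC4 (-0.43) and CORI3 (-2.15), chosen after their values were seen. Of the cold and dehydration genes, 16 of 21 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 9.9e-06, adjusted p = 0.38 with an estimated correlation). P5CS1, which makes the osmolyte proline, rose from 17690 ± 435 to 96680 ± 6570 (SD, n = 2, adjusted p = 1.2e-06), RD29A from 2343 ± 15.9 to 15880 ± 1040 (SD, n = 2, adjusted p = 9.7e-06), and ERD7 and LTI30 changed by 2.78 and 1.93 on the log2 scale. The members that fell were COR413IM1 (-1.29) and the alcohol dehydrogenase gene ADH1 (-2.62), both named by the rule in med8med25. In the salicylate immunity list 11 of 23 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0066, adjusted p = 0.38 with an estimated correlation). The regulators WRKY18 (4.56), CBP60G (3.39), SARD1 (2.51) and GRX480 (4.70) rose, while PR5, a marker of the same response, fell (-1.13, adjusted p = 0.0028).

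Floral repressors passed the list test in hac1hac5 and floral activators did not. Among floral repressors 7 of 16 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.29 with an estimated correlation). The FLC relatives MAF4 and MAF5 rose from 15.8 ± 1.88 to 145.2 ± 48.7 and from 21.42 ± 3.01 to 117.2 ± 2.77 (SD, n = 2, adjusted p = 7.4e-05 and 4.2e-05), and TOE1 rose by 1.07 on the log2 scale. TEM1, which represses FT, fell (-0.84), and total-count scaling gave 12 higher and 1 lower in the list. Of 13 floral activators 6 fell and 0 rose (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.21), against 4 and 1 with total-count scaling. FUL fell from 44.86 ± 4.73 to 10.1 ± 4.26 (SD, n = 2, adjusted p = 0.0025). FT, the mobile flowering signal, was at 16.7 ± 3.76 in Col-0 and 3.964 ± 0.805 in hac1hac5 (SD, n = 2, log2 change -1.83, adjusted p = 0.032), a call lost without the first Col-0 (-1.61), second Col-0 (-2.05), first hac1hac5 (-1.99) or second hac1hac5 library (-1.66) and with a pseudocount of 0.1 (-2.04). AP1 was at 2.879 and 5.327 in Col-0 and listed at 0 in both hac1hac5 libraries. None of the 7 autonomous-pathway genes, which act upstream of FLC, was called (0 adjusted over the list alone; camera adjusted p = 0.94), with FPA at a log2 change of -0.24 (adjusted p = 0.13) and FLD at 0.16 (adjusted p = 0.16). Scaling to totals called 2 of these 7 as higher. Floral organ identity genes had 2 lower of 6 (2 adjusted over the list alone; camera adjusted p = 0.12), and passed with total-count scaling. These were SEP3, at 104.5 ± 9.85 in Col-0 and 7.056 ± 1.58 in hac1hac5 (SD, n = 2, adjusted p = 8.2e-05), and AG, at 5.799 and 5.38 in Col-0 and listed at 0 in both hac1hac5 libraries.

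The auxin, iron, photosynthesis, heat shock and root hair lists passed the list test downwards in hac1hac5. In the auxin response list 18 of 22 fell and 0 rose (18 adjusted over the list alone; camera adjusted p = 5.8e-08, adjusted p = 0.38 with an estimated correlation). The auxin-conjugating enzyme genes GH3.5 and GH3.6 changed by -1.81 and -1.87 on the log2 scale, and IAA19 fell from 2817 ± 94.2 to 306.5 ± 49.9 (SD, n = 2, adjusted p = 3.4e-06). For iron deficiency 15 of 16 fell and 0 rose (16 adjusted over the list alone; camera adjusted p = 1.8e-05, adjusted p = 0.38 with an estimated correlation), including the transcription factor gene BHLH101 (-3.25), the iron regulator BTS (-1.18) and NAS1 (-0.83), which encodes a nicotianamine synthase. BHLH39 was at 355.0 and 744.3 in the Col-0 libraries and 86.35 and 51.72 in hac1hac5 (adjusted p = 3.6e-04), so its level also varied within the wild type. Of the nuclear photosynthesis genes 14 of 23 fell and 0 rose (16 adjusted over the list alone; camera adjusted p = 1.0e-06, adjusted p = 0.44 with an estimated correlation), with the Rubisco small-subunit genes RBCS2B at -1.37 and RBCS1B at -0.87, and 20 fell with total-count scaling. Heat shock genes had 8 of 16 lower and 0 higher (9 lower adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.29 with an estimated correlation), with the chaperone genes HSP70 at -1.41, HSP101 at -1.02 and HSP90.1 at -1.08. Root hair markers had 8 of 10 lower and 0 higher (8 adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.38 with an estimated correlation), with RHS19 at -1.07 and LRX1 at -0.82, and 5 lower with total-count scaling.

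The circadian clock list had 11 of 18 higher and 2 lower members (11 and 3 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.34 with an estimated correlation), with the MYB-like genes RVE6 and RVE8 at 1.11 and 0.91. Other lists did not pass the list test. Ethylene response had 5 higher and 9 lower of 15 (5 and 9 adjusted over the list alone; camera adjusted p = 0.21). Its median log2 change was -0.64 and its mean 0.54, since the ERF genes ERF11 (6.34) and ERF6 (3.95) rose while the ethylene receptor gene ETR2 fell (-1.79). ERF-branch defence had 1 higher and 4 lower of 7 (1 and 4 adjusted over the list alone; camera adjusted p = 0.11), and passed with total-count scaling. ERF1 rose (2.74), the chitinase gene HCHIB fell (-2.20), and the defensin gene PDF1.3 was at 17.41 and 15.07 in Col-0 and listed at 0 in both hac1hac5 libraries. Glucosinolate metabolism had 11 higher and 6 lower of 24 (11 and 8 adjusted over the list alone; camera adjusted p = 0.21). The indole-pathway genes MYB34 (1.19) and CYP83B1 (0.86) rose, and the myrosinase gene TGG2 fell 4.97-fold from 42010 ± 4980 to 8602 ± 2530 (SD, n = 2, adjusted p = 4.0e-05). Flavonoid synthesis had 2 higher and 6 lower of 19 (2 and 6 adjusted over the list alone; camera adjusted p = 0.14), with the anthocyanin activator PAP1 at 2.88 and the entry enzyme CHS at -1.65, and total-count scaling gave 3 higher and 4 lower. Senescence and sugar starvation had 4 higher and 3 lower of 11 (4 and 3 adjusted over the list alone; camera adjusted p = 0.64), with NYE1 at 0.76 and SEN1 at -1.37. Other root markers had 4 lower of 12 (4 adjusted over the list alone; camera adjusted p = 0.092), including THAS1 of thalianol synthesis (-0.74), and this list passed without the second Col-0 library (mean log2 change -0.39) and had 2 lower with total-count scaling. Seed and embryo markers had 1 higher of 11 (0 adjusted over the list alone; camera adjusted p = 0.33), EM1, whose log2 change of 1.81 was not called without the first (1.3) or second Col-0 library (2.31) or the first (1.84) or second hac1hac5 library (1.77), nor with median-of-ratios scaling (1.82), no filter (1.81), the replicate block (1.81) or a pseudocount of 0.1 (1.94). Among other histone acetyltransferases 3 of 10 rose (2 adjusted over the list alone; camera adjusted p = 0.2), and among other Mediator subunits 2 rose and 1 fell of 27 (0 adjusted over the list alone; camera adjusted p = 0.94). Total-count scaling gave 6 higher of the 10, and 5 higher and 0 lower of the 27. All 6 calls of the test reported were lost without at least 1 library: HAC2 (2.89) without the first hac1hac5 library (2.42), HAC4 (0.26) without any of the 4 libraries (0.20 to 0.32) and with the replicate block, HAF2 (1.5) without the first (1.69) or second Col-0 (1.3) or second hac1hac5 library (0.95), MED22A (0.60) without any of the 4 libraries (0.52 to 0.68), and MED19A (0.30) and MED22B (-0.35) without the first Col-0 (0.33 and -0.39), second Col-0 (0.27 and -0.32) or second hac1hac5 library (0.17 and -0.27), and MED22B also with total-count scaling (-0.17).

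The largest increases in hac1hac5 were dominated by genes at 1.474 to 44.8 normalized counts in Col-0. The ERF-family gene AT4G28140 was at 2.949 ± 4.1 in Col-0 and 1564 ± 25.6 in hac1hac5, and RRTF1, another ERF gene, at 1.543 ± 0.831 and 706.3 ± 185 (SD, n = 2); 26.3% of the windows of RRTF1 are free of other annotated genes. DDF1 and CBF1, regulators of drought and cold genes, were at 2.039 ± 0.156 and 3.58 ± 0.981 in Col-0 and 721.1 ± 316 and 855.7 ± 182 in hac1hac5 (SD, n = 2, adjusted p = 3.5e-05 and 5.5e-05). The stress-induced F-box gene FBS1 rose 136-fold to 6234 ± 579 (SD, n = 2, adjusted p = 1.7e-06). AT4G27654, AT2G32200, AT5G45630, AT3G02840 and AT1G05675 completed the 10 genes, at 484.6 to 2214 in hac1hac5 except AT2G32200 at 388.7. Decreases were largest for AT1G64795, at 397.2 and 401.4 in Col-0 and listed at 0 in both hac1hac5 libraries, and none of its read-length windows is free of another annotated gene. AT1G75945 was at 383.9 ± 16.1 in Col-0 and 1.32 ± 0.709 in hac1hac5, and AT3G01345 at 886.5 and 245.7 in the Col-0 libraries and 14.63 and 6.634 in hac1hac5. RTFL18, a small peptide gene that restrains organ growth, fell 34.1-fold from 1367 ± 51.2 to 39.18 ± 3.2 (SD, n = 2, adjusted p = 2.7e-07). The phosphatase gene AT5G02760 fell 21-fold from 19970 ± 168 to 948.8 ± 54.1 (SD, n = 2, adjusted p = 1.9e-06). AT2G37030 of the auxin-induced SAUR family (-5.06), the amino acid transporter gene UMAMIT17 (-5.05), the ethylene synthesis gene ACS4 (-5.02), AT5G57760 (-4.38, with 19.8% of its windows free of other genes) and the transcription factor gene HEC1 (-4.33) were the others.

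In all, 9166 of 23898 genes were called in hac1hac5, 4156 higher and 5010 lower, and 1709 and 1322 of these changed by at least 1 on the log2 scale. Scaling to totals gave 5953 higher and 2844 lower, so the share of higher calls was 45.3% with the authors' scaling and 67.7% with totals. Leaving out a library left its genotype with 1 library, assumed to vary like the others, although replicates differed less in Col-0 than in med8med25. Higher and lower calls were then 2498 and 2525 without the first Col-0 library, 2327 and 2267 without the second, 2628 and 3228 without the first hac1hac5 library, and 2458 and 3171 without the second.

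**Figure D2:**
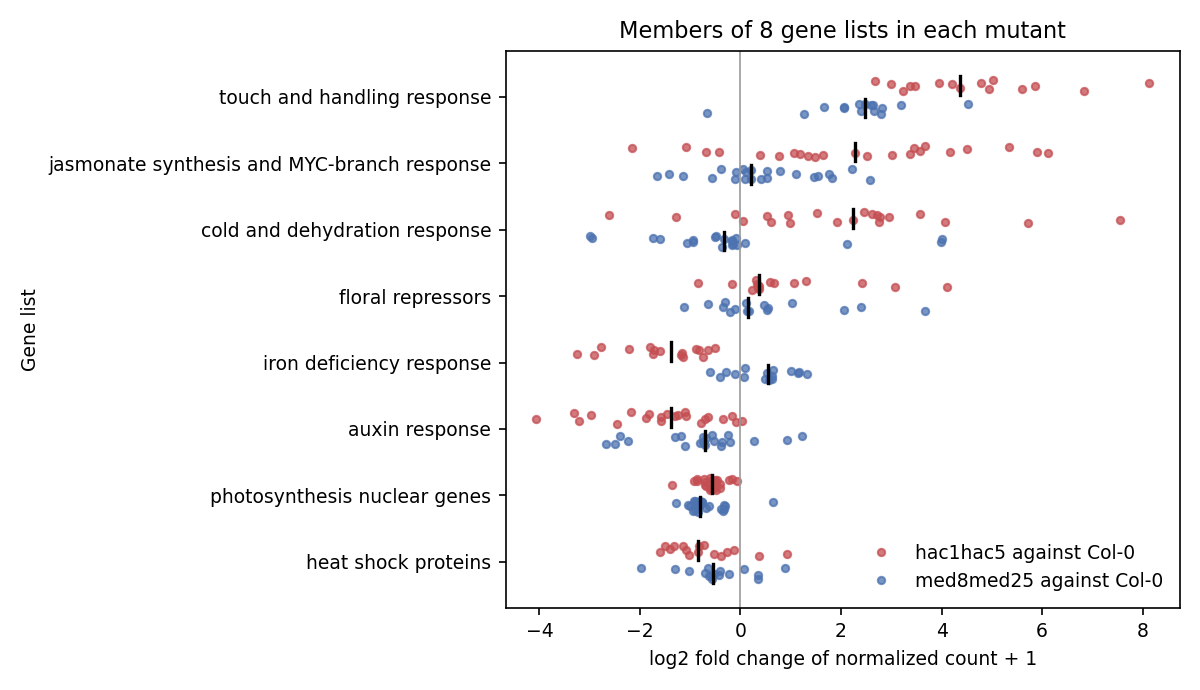
Log2 fold changes of normalized count + 1 against Col-0 for each tested member of 8 gene lists, in hac1hac5 (red) and med8med25 (blue), with a point per gene and a black bar at the median. Touch genes have medians of 4.36 and 2.47, iron deficiency genes of -1.39 and 0.54, and photosynthesis genes of -0.57 and -0.81.

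The comparison of med8med25 with Col-0 asks the same of MED8 and MED25. The touch list passed the list test upwards, and the photosynthesis, auxin response and floral activator lists passed it downwards, all at the preset correlation and none with an estimated correlation. FLC rose 12.8-fold from 19.3 ± 1.43 to 259.2 ± 1.64 normalized counts (SD, n = 2, log2 change 3.68, SE 0.17, adjusted p = 9.5e-06), with 12.0% of its windows free of other genes. SOC1, a central activator of flowering that FLC represses, fell from 3021 ± 16.6 to 819.2 ± 48.0 (SD, n = 2, log2 change -1.88, adjusted p = 7.4e-05). ASN1, the dark- and starvation-induced asparagine synthetase gene, fell 6.39-fold from 9446 ± 558 to 1492 ± 301 (SD, n = 2, adjusted p = 1.2e-05). DIC2, a mitochondrial dicarboxylate carrier gene, rose 26.7-fold from 120.2 ± 5.99 to 3235 ± 45.5 (SD, n = 2, adjusted p = 5.7e-08).

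Of the touch and handling genes 14 of 15 rose (14 adjusted over the list alone, camera adjusted p = 2.4e-10, adjusted p = 0.44 with an estimated correlation), among them ZAT10 (log2 change 4.53), WRKY40 (3.2), SZF1 (2.65) and SZF2 (2.06). The remaining member, CML38, a calmodulin-like gene, was at 111.7 ± 13.2 in Col-0 and 76.6 ± 45.4 in med8med25 (SD, n = 2, adjusted p = 0.2). Nuclear photosynthesis genes had 16 of 23 lower and 1 higher (17 and 1 adjusted over the list alone; camera adjusted p = 4.7e-09, adjusted p = 0.46 with an estimated correlation). LHCB2.3, which encodes an antenna protein, fell from 62740 ± 1970 to 26040 ± 4480 (SD, n = 2, adjusted p = 4.1e-04), and LHCA3 had a log2 change of -1.05 that was not called without the first (-1.07) or second Col-0 library (-1.03). In the auxin response list 15 of 22 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 2.1e-04, adjusted p = 0.46 with an estimated correlation), with GH3.5 at -1.11, IAA19 at -2.23 and IAA29 at -2.67. The 2 that rose were the lateral-root genes LBD16 (0.92) and LBD18 (1.23), chosen after their values were seen.

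Among floral activators 5 of 13 fell and 0 rose (6 lower adjusted over the list alone; camera adjusted p = 0.0032, adjusted p = 0.44 with an estimated correlation). FUL fell from 44.86 ± 4.73 to 5.483 ± 0.206 (SD, n = 2, adjusted p = 0.0011). FT was at 4.642 ± 4.01 (SD, n = 2, log2 change -1.84, adjusted p = 0.041), a call lost without the first (-1.62) or second Col-0 (-2.06), the first or second hac1hac5 (-1.84) or the second med8med25 library (-1.05), and with total-count scaling (-1.65), median-of-ratios scaling (-1.76), a pseudocount of 0.1 (-2.13) or only the 2 genotypes in the fit (-1.84). Of the floral repressors 7 of 16 rose and 2 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.093). MAF4 rose to 69.87 ± 11.6 and MAF5 to 115.9 ± 4.63 (SD, n = 2, adjusted p = 0.0012 and 1.1e-04), and TEM1 fell (-1.13). No autonomous-pathway gene of 7 was called (0 adjusted over the list alone; camera adjusted p = 0.26), with FVE at 0.16 (adjusted p = 0.16) and FY at 0.21 (adjusted p = 0.17), while total-count scaling called 2 higher. Floral organ identity genes had 1 higher and 2 lower of 6 (1 and 2 adjusted over the list alone; camera adjusted p = 0.14), and passed with total-count scaling. SEP3 fell to 6.18 ± 2.17 (SD, n = 2, adjusted p = 1.6e-04), and AG was listed at 0 in both med8med25 libraries, with a call lost without either Col-0 library.

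The hormone and cold lists moved in mixed directions. Cold and dehydration genes had 3 higher and 8 lower of 21 (3 and 8 adjusted over the list alone; camera adjusted p = 0.034, adjusted p = 0.67 with an estimated correlation). The call was lost without the second med8med25 library, which gave a mean log2 change of 0.11 in place of -0.22, and with a filter of 1 CPM in at least 2 libraries (-0.22). COR413IM1 (-2.95), the dehydrin gene RAB18 (-1.74), ADH1 (-2.99) and P5CS1 (-1.07) fell, while CBF2, a regulator of the cold response, was at 40.29 ± 5.11 in Col-0 and 754.6 ± 524 in med8med25 (SD, n = 2, adjusted p = 3.5e-04). ERF-branch defence had 1 higher and 4 lower of 7 (1 and 5 adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.44 with an estimated correlation), and the call was lost without the second med8med25 library (mean log2 change -1.77) and with the 1 CPM filter (-1.38). The transcription factor gene ORA59 fell from 74.01 ± 29.6 to 3.255 ± 0.718 (SD, n = 2, adjusted p = 0.0012), HEL changed by -1.54 on the log2 scale, and PDF1.3 was listed at 0 in both med8med25 libraries. Ethylene response had 4 higher and 10 lower of 15 (4 and 10 adjusted over the list alone; camera adjusted p = 0.041, adjusted p = 0.44 with an estimated correlation), with EBF2 at -1.54 and ETR2 at -1.34 but ERF5 and ERF6 at 1.69 and 2.04. Its call was lost without the first Col-0 (mean log2 change 0.00), either hac1hac5 (-0.01) or the second med8med25 library (0.05), with the 1 CPM filter (-0.01) and with only the 2 genotypes in the fit (-0.01). Jasmonate synthesis and MYC-branch genes had 10 higher and 4 lower of 23 (10 and 5 adjusted over the list alone; camera adjusted p = 0.13), and passed without the second med8med25 library (mean log2 change 0.63). AOC3 rose (1.76), while JAZ6 (-1.14) and the MYC-branch storage protein genes VSP1 (-1.42) and VSP2 (-1.67) fell. Salicylate immunity had 7 higher and 2 lower of 23 (8 and 2 adjusted over the list alone; camera adjusted p = 0.13), with SARD1 at 2.49 and CBP60G at 2.11, and passed without the first med8med25 library (mean log2 change 0.45).

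The iron, glucosinolate, flavonoid, senescence, heat shock and clock lists did not pass the list test in med8med25. Iron deficiency genes had 5 higher of 16 (5 adjusted over the list alone; camera adjusted p = 0.099), and the list passed without the second Col-0 library (mean log2 change 0.73) or the first med8med25 library (0.63) and with limma voom (0.45). The iron reductase gene FRO2 was at 210.2 ± 75 in Col-0 and 450.1 ± 45.9 in med8med25 (SD, n = 2, log2 change 1.14, adjusted p = 0.0094), a call lost without the first Col-0 library (0.77). Glucosinolate metabolism had 4 higher and 10 lower of 24 (5 and 11 adjusted over the list alone; camera adjusted p = 0.14), with TGG2 at -2.49, CYP79B3 at -0.77, MAM1 at -1.52 and MAM3 at -1.02, and passed without the second med8med25 library (mean log2 change -0.42). Total-count scaling gave 5 higher and 6 lower and moved the median from -0.13 to 0.02. Flavonoid synthesis had 4 higher and 7 lower of 19 (4 and 8 adjusted over the list alone; camera adjusted p = 0.05), with CHS at -0.83, FLS1 at -1.38 and PAP1 at -1.81, and passed without the second Col-0 library (mean log2 change -0.57) and with median-of-ratios scaling, no filter, the replicate block or total-count scaling. Senescence and sugar starvation had 1 higher and 4 lower of 11 (1 and 6 adjusted over the list alone; camera adjusted p = 0.05), with BCAT2 at -2.42 and SEN1 at -1.25. It passed without the second Col-0 library (mean log2 change -0.87) or the first (-0.69) or second med8med25 library (-0.98), and with the same settings as flavonoid synthesis or limma voom. Heat shock genes had 3 of 16 lower (3 adjusted over the list alone; camera adjusted p = 0.099), with HSP18.2 at -1.97, and passed with total-count scaling (mean log2 change -0.33). The circadian clock had 3 higher and 7 lower of 18 (3 and 7 adjusted over the list alone; camera adjusted p = 0.55), against 4 higher and 3 lower with total-count scaling. The morning gene LHY rose from 2398 ± 60.9 to 6466 ± 169 (SD, n = 2, adjusted p = 1.1e-05) and ELF4 fell (-2.62).

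Root hair markers had 2 higher of 10 (2 adjusted over the list alone; camera adjusted p = 0.26), with the cell wall gene PRP3 at 0.61, a call lost without the second Col-0 library (0.53). Other root markers had 5 higher and 4 lower of 12 (5 and 5 adjusted over the list alone; camera adjusted p = 0.92), with a median log2 change of 0.18 and a mean of -0.13. CASP1 of the endodermis rose (0.74), and THAS1 (-1.38), THAH (-1.53) and the root glucosidase gene PYK10 (-1.18) fell. Seed and embryo markers had 1 higher and 2 lower of 11 (1 and 2 adjusted over the list alone; camera adjusted p = 0.92). SESA1 was at 3.844 and 6.399 in Col-0 and listed at 0 in both med8med25 libraries, and CRU2 was listed at 0 in the Col-0 libraries and at 2.682 and 2.812 in med8med25. Other histone acetyltransferases had 1 higher and 2 lower of 10 (1 and 2 adjusted over the list alone; camera adjusted p = 0.92), against 2 higher and 0 lower with total-count scaling. Their median log2 change of 0.01 and mean of 0.15 differ in sign from the list test. Other Mediator subunits had 1 higher and 5 lower of 27 (1 and 5 adjusted over the list alone; camera adjusted p = 0.26), and total-count scaling gave 4 higher and 0 lower, so no direction is given for MED6, MED7B, MED10B and CDKE1 beyond log2 changes of -0.37, -0.37, -0.45 and -0.30.

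The 10 largest increases in med8med25 included ZAT10, CBF2, FLC and DIC2 from above. AT4G27657, AT5G45630, AT3G10930, AT3G29000 and AT5G17350 were the others besides AT3G01345, and changed by 3.55 to 4.06 on the log2 scale. AT3G01345, at 886.5 and 245.7 in the Col-0 libraries, was at 6809 and 6780 in med8med25 (adjusted p = 0.0014). Among decreases, AT1G64795, with no window free of other genes, was at 397.2 and 401.4 in Col-0 and 2.539 and 0.914 in med8med25, and AT4G01390 at 284.0 ± 8.05 and 0.4902 ± 0.643 (SD, n = 2). AT3G16670 fell from 569.2 ± 9.63 to 3.761 ± 1.35 and AT5G22580 19.7-fold from 2050 ± 25.9 to 104.0 ± 21.8 (SD, n = 2, adjusted p = 3.5e-06 and 3.6e-06). RTFL18 fell 19.1-fold, and AT1G31690 (-4.67), AT4G14060 (-4.46), AT5G37990 (-4.33), the amino acid transporter gene UMAMIT14 (-4.17) and AT2G37030 (-3.89) completed the group.

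In all, 6350 genes were called in med8med25, 2929 higher and 3421 lower, and 790 and 972 of these changed by at least 1 on the log2 scale. Scaling to totals gave 5203 higher and 1965 lower, a share of higher calls of 72.6% against 46.1%. The counts were lower without either Col-0 library than without either med8med25 library. Each of these fits leaves 1 library in a compared genotype. The genotypes share an estimate of the spread, and replicates differed least in Col-0 (SD of the log2 difference 0.18) and most in med8med25 (0.308). Leaving out a Col-0 library takes the least variable pair out of that estimate, and leaving out a med8med25 library the most variable pair. The difference in counts goes with this, and no other cause was tested. With only med8med25 and Col-0 in the fit, 4919 genes were called.

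The comparison of the 2 mutants' changes asks whether the same transcripts differ from Col-0 in both mutants. DIC2, ZAT10, CBF2, AT4G27657 and AT5G45630 were the genes with the largest increase in both, and AT1G64795, RTFL18, AT4G01390, UMAMIT14 and AT2G37030 those with the largest decrease in both. RTFL18 was at 1367 ± 51.2 in Col-0, 39.18 ± 3.2 in hac1hac5 and 70.86 ± 6.06 in med8med25, and UMAMIT14 at 285.9 ± 36.9, 17.31 ± 10.5 and 15 ± 2.72 (SD, n = 2). MAF4, MAF5, TEM1 and SEP3 were called in the same direction in both mutants. Genes called higher in both numbered 1237, against 509.4 for independent lists, and genes called lower in both 1766, against 717.2. Opposite calls numbered 626, against 1209. VSP1, P5CS1, PAP1 and RD29A, which rose in hac1hac5, fell in med8med25, although the RD29A call in med8med25 was lost without the first (-0.94) or second Col-0 library (-0.93).

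Log2 fold changes of the 2 mutants correlated across 23898 genes at r = 0.506, and at 0.546 over 15751 genes with at least 5 CPM, and genes are not independent replicates. Unchanged groups simulated against the same Col-0 libraries gave a mean r of 0.502 (0.481 to 0.524 in 100 simulations). In these simulations the shared controls alone set r, so a similar r in the data cannot tell shared changes from shared controls. The covariance was 0.316 against 0.043 in the simulations, a difference of 0.273, and simulated overlaps held at most 2 genes per direction. Giving each mutant its own controls would leave 1 Col-0 library per mutant and was not done, so part of the excess overlap may come from the shared controls. Growth or harvest conditions that set both mutants apart from Col-0 could also add to the overlap. They cannot be told apart from an effect of the mutations. Without the first and second Col-0 library the counts were 480 and 428 higher in both, 614 and 570 lower in both, and 104 and 100 opposite. Without the first and second hac1hac5 library they were 781 and 747 higher and 360 and 321 opposite. Total-count scaling gave 2396 higher and 979 lower in both.

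**Figure D3:**
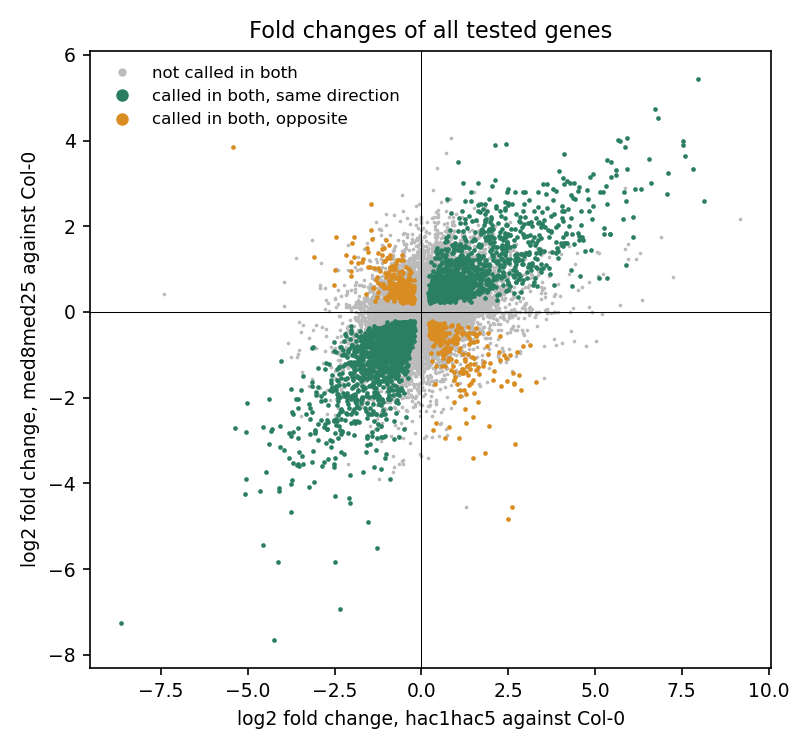
Log2 fold changes against Col-0 of 23898 tested genes in hac1hac5 (horizontal) and med8med25 (vertical), with a point per gene, green for genes called in both mutants in the same direction and orange for opposite calls. The 1237 genes higher in both and 1766 lower in both lie along the diagonal, and both axes share the same Col-0 libraries.

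Set directly against hac1hac5, med8med25 seedlings had most jasmonate, cold and touch genes lower and most iron and auxin genes higher. In the cold and dehydration list 19 of 21 members were lower in med8med25 than in hac1hac5 and 0 higher, P5CS1 differing 11.5-fold. In the jasmonate synthesis and MYC-branch list 19 of 23 were lower and 3 higher, with OPR3 at 9233 ± 379 in hac1hac5 and 804.7 ± 80.7 in med8med25 (SD, n = 2, adjusted p = 8.4e-07). Of the touch genes 14 of 15 were lower, CML38 at 3687 ± 784 and 76.6 ± 45.4 (SD, n = 2, adjusted p = 1.7e-05). Iron deficiency genes were higher in 15 of 16 cases, with BHLH39 at 69.04 ± 24.5 in hac1hac5 and 769.2 ± 175 in med8med25 (SD, n = 2, adjusted p = 1.8e-04), and 17 of 22 auxin response genes and 8 of 10 root hair markers were higher. Neither FLC (log2 difference -0.42, adjusted p = 0.074) nor FT (-0.02, adjusted p = 0.99) differed between the mutants by this test, whereas SOC1 was lower in med8med25 (-1.37, adjusted p = 2.0e-04).

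The largest differences between the mutants were in AT3G01345, 622-fold higher in med8med25, and in AT1G75945, at 1.32 ± 0.709 in hac1hac5 and 509.6 ± 2.73 in med8med25 (SD, n = 2). The long noncoding RNA gene AT1G07373 and the root myrosinase genes BGLU35 and BGLU34 were also higher in med8med25 (log2 differences 4.2, 3.71 and 3.6). TPS04, a terpene synthase gene of the volatile defence response, was at 282.8 ± 41.9 in hac1hac5 and 0.9839 ± 1.29 in med8med25 (SD, n = 2). AT4G12490 was at 267.5 ± 230 and 0.6239 ± 0.882 (SD, n = 2) and lost its call with limma voom (log2 difference -7.88). AT4G28140, CML38 and the ERF gene ERF53 (-6.09) were the other genes lower in med8med25. In all, 9887 genes differed, 4999 higher and 4888 lower in med8med25, and 1074 and 1634 by at least 1 on the log2 scale. Without the first and second hac1hac5 library the counts were 3234 and 3163 higher and 2971 and 2820 lower.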

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

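Results with limma voom and with total-count scaling were chosen after seeing the data, and the other settings before. No result that was called, either in the test reported or under a setting, turned the direction of its test, but 2 lists called in med8med25 changed the sign of their mean without the second med8med25 library, cold from -0.22 to 0.11 and ethylene response from -0.01 to 0.05, the latter also with median-of-ratios (0.01) and total-count scaling (0.15). Uncalled results did turn, such as the med8med25 lists of other histone acetyltransferases and other root markers with total-count scaling. Among named genes 4578 results kept their side of the threshold, 283 lost the call and 49 gained it, and among lists the numbers were 696, 28 and 42. Most of the losses among genes came without a Col-0 or a hac1hac5 library. Fewer came without a med8med25 library, although that also leaves fewer samples. Leaving out a med8med25 library takes the most variable pair out of the shared estimate of the spread, and no other cause was tested. Median-of-ratios scaling, no filter, a pseudocount of 0.1, fits of 2 genotypes and limma voom left every count of genes and the correlation within 1.5 times or its tolerance. In hac1hac5, in med8med25 and between the mutants, voom kept 98.9%, 95.3% and 98.4% of the calls. Fits of 2 genotypes kept 99.3%, 75.5% and 76.9%, and called 10443, 4919 and 7645 genes. The shared estimate of the spread assumes that the genotypes vary alike. The SD of the log2 difference between replicates was 0.18 in Col-0, 0.227 in hac1hac5 and 0.308 in med8med25. With the shared estimate fewer genes were called in hac1hac5 (9166) and more in med8med25 (6350) than in fits of 2 genotypes. The planned count-model tests were not run, on the deposited values or on the recovered reads, and limma voom was run in their place, so their calls are unknown.

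Leaving out a library gave 2327 to 4746 higher and 2267 to 5723 lower in hac1hac5, 816 to 3006 and 1095 to 3538 in med8med25, 3163 to 4756 and 2820 to 4918 between mutants, 428 to 1428 and 570 to 1856 in both mutants and 100 to 898 opposite, with r from 0.455 (first med8med25 library out) to 0.548 (first Col-0 library out). A minimum log2 change of 1 left, in that order, 1709, 1322, 790, 972, 1074, 1634, 424, 443 and 83, by its construction. Total-count scaling gave 2844 lower in hac1hac5, 5203 higher and 1965 lower in med8med25, and 2396 higher and 979 lower in both, by the shift of the median. Of the lists, 11 passed in hac1hac5 and 7 in med8med25. With an estimated correlation 0 and 0 passed, and with fry, which makes no comparison with other genes, 18 and 15. Estimates ran up to 0.912 (photosynthesis), but lists with an estimate below the preset 0.01 lost the call too. Among these were floral repressors (-0.005) and heat shock genes (-0.042) in hac1hac5, and floral activators (-0.015) in med8med25. Loss of a call under this setting therefore does not by itself show correlation between members. In med8med25 the 1 CPM filter left 4, without cold, ERF-branch defence and ethylene response, and total-count scaling 12, and the cause was not tested.

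With the replicate number as a block, the replicate block fits called 8234, 5357 and 9004 genes and kept 89.1%, 83.3% and 90.3% of the calls. Deviations of same-numbered libraries correlated at -0.023, -0.129 and -0.228 across 18807 genes, and the labels do not say that a number marks a shared day, so the block was not used.

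Depth limits weakly expressed genes: FT, AP1, AG and the seed genes SESA1 and CRU2 rest on few reads.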

Other observations

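The gene families in the next 2 paragraphs, the tests of the touch genes and the tests of genes near absent in a genotype were chosen only after the result was seen. The 2 tests of overlap and of repeated sequence were written before the result was seen.

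Families picked from gene symbols were counted by member, leaving out RPT2, CRK1 and SAUR21, which the reference describes as other kinds of protein, and no family was tested as a group. Members shown under another name or by gene ID, such as AT2G37030 of the SAUR family, were not counted. Some members also belong to the gene lists above, such as WRKY18, WRKY33 and WRKY40, and the auxin response list also holds SAUR genes. Counts of these families therefore partly restate the lists. Among 12 families, 12 of 14 FLA genes (fasciclin-like arabinogalactan proteins) fell and 0 rose, with FLA2 at 5472 ± 278 normalized counts in Col-0 and 1068 ± 95.2 in hac1hac5 (SD, n = 2, limma adjusted p = 5.7e-06). Of the 9 beta-tubulin genes 8 fell, TUB5 from 7173 ± 351 to 3356 ± 144 (SD, n = 2, adjusted p = 6.5e-05). XTH genes, which remodel xyloglucan, had 16 of 26 lower and 3 higher, AGP genes 16 of 26 lower and 3 higher, SAUR genes 14 of 14 lower and LSH genes 7 of 8 lower. Over all 18807 genes with at least 1 CPM, 24.7% fell and 19.5% rose. In med8med25 the counts were 2 lower and 1 higher for FLA, 1 lower for TUB, 4 lower and 5 higher for XTH, 11 lower and 2 higher for AGP, 8 lower for SAUR and 4 lower for LSH, against 16.7% lower and 14.2% higher over all these genes. Family medians kept their sign with total-count scaling in hac1hac5, while in med8med25 those of FLA (-0.09 and 0.07) and TUB (-0.01 and 0.15) flipped.

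The PUB, WRKY, CRK and MAPKKK families had more higher than lower members in hac1hac5. Of 20 PUB genes, plant U-box ubiquitin ligases, 15 rose and 0 fell, PUB24 from 95.57 ± 1.54 to 1081 ± 123 (SD, n = 2, limma adjusted p = 1.0e-05). WRKY transcription factor genes had 24 of 48 higher and 2 lower, CRK receptor kinase genes 13 of 21 higher and 2 lower, and MAPKKK genes 7 of 11 higher, MAPKKK18 from 50.5 ± 14.9 to 989.2 ± 8.76 (SD, n = 2, adjusted p = 1.2e-05). In med8med25 the higher and lower counts were 4 and 1 for PUB, 16 and 4 for WRKY, 7 and 1 for CRK, and 0 and 1 for MAPKKK, whose median flipped with total-count scaling (-0.04 and 0.09). The proteasome RPT genes had 4 of 8 lower in hac1hac5 and 0 called in med8med25. MCM genes of DNA replication had 2 of 8 lower in hac1hac5 and 4 higher in med8med25. Differences between the mutants were not tested by family.

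Touch and handling genes were higher in both mutants, with list medians on the log2 scale of 8.02 and 7.75 in the Col-0 libraries, 12.56 and 12.88 in hac1hac5, and 10.65 and 11.06 in med8med25. The authors' scaling is argued against as the whole cause, since at least 14 of 15 members stayed higher with total-count scaling. Handling that varied from sample to sample stays open: the largest difference within a genotype was 0.41, against 2.97 for the smaller mutant difference, but the 2 libraries of a genotype may have been handled together. Growth or harvest conditions that differed between the genotypes cannot be told apart from an effect of the mutations, because each genotype may have been grown or harvested as a block, and the 14 members above both Col-0 libraries in all 4 mutant libraries only restate the pattern. An effect of the mutations themselves remains an untested hypothesis beside it.

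Of 27426 protein-coding genes, 3354 (12.2%) had no read in any library, among them MYC2, ERF105 and SPL15, which have no read-length window free of other annotated exons. Reads overlapping more than 1 annotated gene may not have been counted: 85.6% of the 534 genes without a free window had no read, against 9.9% of 22185 genes with at least 90% free and unique windows. This fell short of the 90% set beforehand, and the annotation used here may differ from the authors', so the question stays open. Reads matching several places may also have been left out, with no read for 60.0% of 230 genes without a unique window. SAG12, with every window free, also had no read, which neither explanation covers. The same holds for 2187 of the 3354 genes, which had at least 90% free and unique windows.

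There were 7 genes with at most 3 reads in the 2 libraries of a genotype and at least 5 CPM in another: AT1G64795, AT1G75945, AT4G01390, TPS04, AT4G12490, AT2G32200 and RRTF1. Loss or exchange of a chromosome segment could empty a gene together with its neighbours. At most 3 of the 10 nearest tested genes changed alike (AT4G12490), and 0 did so for AT1G64795, AT1G75945 and RRTF1. This is below the 5 set as the sign of such a loss, but above the bound of 1 set to exclude it for all 7 genes. A loss of fewer genes would not reach 5. The larger count of the 2 mutant comparisons was kept. The 3 may thus come from hac1hac5, where AT4G12490 was not absent (267.5, against 34.18 in Col-0), and would then say nothing about a loss. A DNA or chromatin difference of the gene itself between the plant lines remains possible for these 7 genes and cannot be told apart from an effect on transcription without genome sequence of the lines.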
